A study of Mus musculus with 2 samples.

How the data were processed

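Polyadenylated RNA from the pancreas of 1 adult female C57BL/6J mouse, 10 weeks old, was analysed in 2 technical replicate libraries. Per the labels, both libraries come from 1 biological sample, RNA was extracted with a lipid tissue kit, and replicate 2 was made in May 2015; no date is given for replicate 1 in the sources used here. The labels give a size range for the library fragments without a unit. The libraries form 1 group, so no comparison between conditions exists.

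Per the deposited README files, the values rest on genome build mm10 and the GENCODE M4 annotation, and signal tracks of both strands were made from the same alignments. The aligner, the quantifier and their versions are not given in the sources used here. Per the file headers, the deposited tables hold an expected count per gene and per transcript, which is an estimate and need not be whole, together with a posterior mean count and its standard deviation. The deposited TPM corrects the expected count for effective length and is scaled to the same total in every file. Recomputing TPM from the count and the effective length matched the deposited value within 1% for 100% of genes at 1 TPM or more. The deposited FPKM was used only as an alternative. The deposited posterior mean TPM, entered here as a signal, was used as an alternative. Its credibility bounds belong to the posterior mean and do not bracket the TPM, so they were not used as the intervals that had been planned. The deposited percent of each isoform within its gene came with the transcript tables, and isoform shares were recomputed from transcript TPM.

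Each table holds 43346 gene rows, 97 spike-in rows and 26248 numbered rows. The spike-in and numbered rows hold no counts in either library and were left out. Gene symbols and positions came from GENCODE M21 on GRCm38, the assembly that mm10 names, and 42462 of the 43346 gene identifiers matched. Spink3 and Tf of the fixed lists were found under the symbols Spink1 and Trf, and Iglc1 was not matched. The expected counts summed to 9441559 in replicate 1 and 9797569 in replicate 2.

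Expected counts were rounded to whole numbers. Library totals were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3. With 1 library on each side edgeR's quasi-likelihood model has no residual degrees of freedom, so each gene was tested with a two-sided exact binomial test of its counts given their sum. Genes with a mean of at least 10 counts were tested, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05 and a log2 ratio of 1 or more in size, with 0.5 added to both counts. This test compares these libraries and not conditions, and it holds counting error only. Intervals of a ratio are exact Clopper-Pearson intervals at 95%, and a count of 0 was bounded at 3 counts per library.

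Before the data were examined, 29 gene lists with 441 symbols were fixed, along with the rule for the genes named: the 25 most abundant genes, the 4 most abundant members of each list, the 10 called genes with the highest and the 10 with the lowest log2 ratio among those with 100 counts or more where the gene is higher, and the 5 genes with the most different main isoform share. List members named outside this rule were chosen after their values were seen. The median log2 ratio of each list was placed among 10000 random lists of the same size matched on mean count in 20 bins. A list was called when it lay in the lowest or highest 2.5% of these, and lists with under 3 tested members got no call. Isoform shares were compared for genes with a mean of at least 100 counts and 2 or more transcripts.

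GC content came from the dominant transcript of each gene and was found for 99.8% of the tested genes. A smooth trend of the log2 ratio on GC content and transcript length was fitted on tested nuclear genes. Nuclear copies of mitochondrial genes were found with BLAST+ 2.17.0 at 95% identity over 90% of the copy. The alternatives covered scaling with library totals, DESeq2 1.42.0 size factors and upper quartile factors, count filters, posterior mean values, thinning, edgeR exact tests with assumed dispersions of 0.01 and 0.1, the GC and length trend, pseudocounts and leaving out a library. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

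The tests were tried on counts drawn for the 43346 genes from the means and sizes of these libraries, with 200 genes changed. In this simulation of replicate 2 against replicate 1, with 12433 genes tested, 36.7% of the tested genes changed 2-fold and 91.0% of those changed 4-fold were called in the planted direction. A 2-fold change sits at the size threshold, so counting error alone puts part of these genes below it. Of the genes changed 2-fold, 60.2% had an adjusted p under 0.05 in the exact binomial test. Of 12235 unchanged genes 2 were called. These counts came from a Poisson model and hold counting error only, which is what the test assumes. The log2 ratio of the real libraries had a spread of 0.63, against 0.23 in Poisson counts, so these rates do not carry over to them.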

Results

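Polyadenylated RNA from the pancreas of 1 adult female C57BL/6J mouse, the reference inbred strain, was sequenced as 2 technical replicate libraries. The deposited expected counts summed to 9441559 in replicate 1 and 9797569 in replicate 2. Values are deposited TPM, given per library or as mean ± SD over the 2 libraries, and this SD is technical. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules. Coordinates are those of GRCm38, and each interval spans the whole annotated gene with its exons, introns and UTRs.

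The first question was what the transcript pool of this pancreas holds. Digestive enzymes and zymogen granule proteins of the acinar cell took 29.2% ± 2.69 of all TPM (SD, n = 2 technical libraries). Of the 34 genes in the list, 33 reached 1 TPM in both libraries, with list medians of 5334 TPM in each. By the mean of the libraries the chymotrypsinogen gene Ctrb1 came first (chromosome 8, 111686519 to 111691010), at 32765 ± 7503 TPM (SD, n = 2), though Amy2a5 was above it in replicate 1 and Cela2a in replicate 2. The elastase gene Cela2a (chromosome 4, 141814962 to 141826160) reached 31718 ± 21235 TPM, and colipase, Clps (chromosome 17, 28558149 to 28560766), 24313 ± 420 TPM (SD, n = 2 for both).

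Amylase was spread over 4 nearly identical genes on chromosome 3. Amy2a2 (113345055 to 113356658) held 27264 ± 1361 TPM and Amy2a5 (113247178 to 113258837) 26269 ± 2678 TPM (SD, n = 2). Amy2a3 and Amy2a4 lay at 26181 ± 1847 and 26904 ± 1349 TPM. The deposited posterior standard deviation of the Amy2a2 count was 320646 in replicate 1, against an expected count of 383264, so the division of reads among the copies was uncertain. Together the 4 copies took 10.7% ± 0.723 of TPM (SD, n = 2). The fixed enzyme list holds only Amy2a5 of these copies, and with all 4 it took 37.2% ± 2.24 of TPM, an alternative chosen after seeing the data.

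Other acinar products among the 25 most abundant genes were Cela1 at 17406 ± 7381 TPM, the lipase gene Pnlip at 16832 ± 1863, the carboxypeptidase gene Cpa1 at 15037 ± 4111 and the ribonuclease gene Rnase1 at 14246 ± 8546 (SD, n = 2). The trypsinogen genes Prss2 and Try4 reached 12841 ± 2906 and 11757 ± 3046 TPM, Zg16 12140 ± 1831 and Ctrl 11695 ± 620. Of the islet genes only Ins2, one of the insulin genes, was among these 25, at 15973 ± 2834 TPM. The remaining places went to mitochondrial mRNAs (mt-Atp8, mt-Co1, mt-Cytb, mt-Co2, mt-Nd1 and mt-Atp6), to Gm10925 and Gm28661, which are nuclear copies of mt-Atp6 and mt-Co2 on chromosome 1, and to the lincRNA Gm42418.

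The 10 most abundant genes took 46.9% ± 12.9 of TPM (SD, n = 2), with 37.7% in replicate 1 and 56.0% in replicate 2. Gm42418 (chromosome 17, 39846958 to 39848788) alone held 16.9% of counts in replicate 1 (95% exact interval 16.90 to 16.95) and 42.8% in replicate 2 (42.77 to 42.83). Genes of the mitochondrial genome held 17.6% of counts (17.60 to 17.65) in replicate 1 and 3.17% (3.16 to 3.18) in replicate 2. Without the mitochondrial genes, their nuclear copies, Gm42418, Gm26917 and Lars2, 5801288 and 4644835 counts were left for all other genes. At 1 TPM or more, 10332 genes were detected in both libraries, of which 9964 are protein coding, with 11450 in replicate 1 and 11006 in replicate 2.

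**Figure D1:**
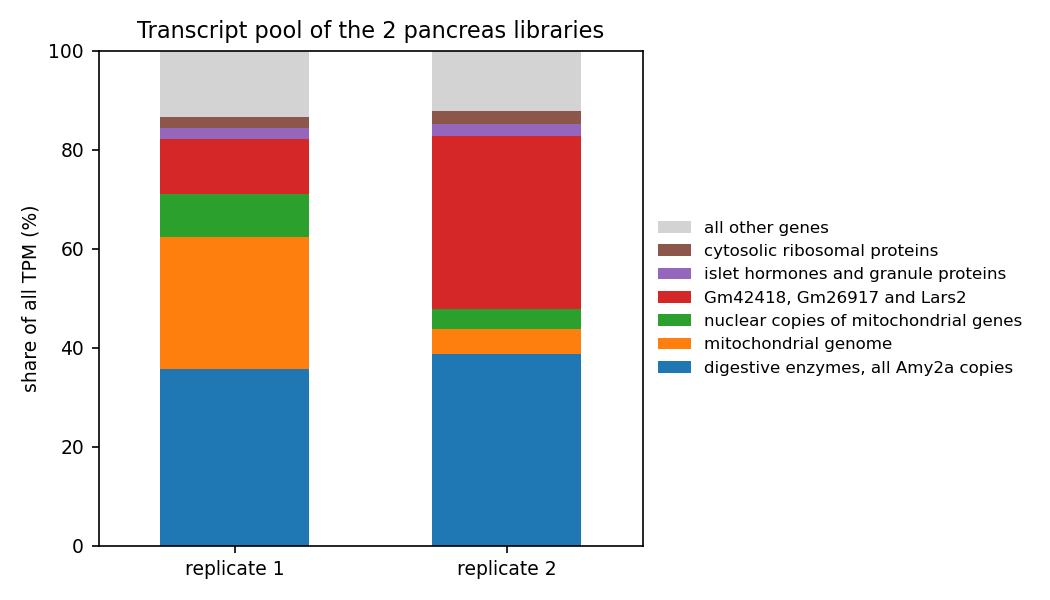
Share of all TPM (%, y axis) taken by gene groups in each technical library (x axis), as stacked bars that sum to 100%. Gm42418, Gm26917 and Lars2 took 11.2% in replicate 1 and 35.0% in replicate 2, and the mitochondrial genome 26.7% and 5.05%.

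The second question was which cell types of the pancreas the libraries hold. Of the 29 fixed lists, 22 had a median of 1 TPM or more in both libraries. Islet hormones and granule proteins had medians of 61.6 TPM in replicate 1 and 69.6 TPM in replicate 2, with 16 of 17 members at 1 TPM or more in both. Besides Ins2, the glucagon gene Gcg reached 2900 ± 1887 TPM, the insulin gene Ins1 2387 ± 326 and the amyloid peptide gene Iapp 871 ± 60.9 (SD, n = 2). The ratio of Ins2 to Ins1 TPM was 6.48 in replicate 1 and 6.87 in replicate 2, while that of Ins2 to Gcg was 3.30 and 11.5. The list of beta cell function had medians of 5.67 and 5.09 TPM, led by Ero1lb at 55.3 ± 0.955 and the islet phosphatase gene G6pc2 at 41.3 ± 2.92 TPM. Endocrine transcription factors lay lower, with medians of 3.38 and 2.28 TPM, with Pax6 at 13.2 ± 9.53 and Isl1 at 7.60 ± 6.07 TPM.

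Acinar transcription factors had medians of 7.60 and 5.97 TPM. Rbpjl, a subunit of the acinar PTF1 complex, reached 242 ± 73.6 TPM, Xbp1 104 ± 7.35, Bhlha15 27.5 ± 2.34 and Ptf1a 8.46 ± 0.778 (SD, n = 2). The protein folding list of the endoplasmic reticulum had medians of 54.6 and 53.7 TPM, led by the pancreatic disulfide isomerase Pdia2 at 1268 ± 407 TPM and followed by P4hb at 301 ± 14.5. Amino acid metabolism genes had medians of 16.5 and 12.9 TPM, with Gatm at 79.9 ± 28.7 and Cbs at 62.5 ± 0.0566. In the secretagogue and exocytosis list, with medians of 4.11 and 2.98 TPM, the cholecystokinin receptor gene Cckar reached 39.6 ± 11.8 and Stxbp2 46.8 ± 2.72 TPM. The Reg family had medians of 7.49 and 3.72 TPM, with Reg1 at 2995 ± 419 TPM and Reg3d at 105 ± 53.6.

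Duct markers had medians of 18.0 and 8.90 TPM, led by Tff2 at 1624 ± 453 and Clu at 182 ± 35.1 TPM. Endothelial markers had medians of 35.4 and 24.3 TPM, led by Plvap at 113 ± 19.8. Fibroblast and stellate markers had medians of 25.9 and 22.0 TPM, with Dcn at 330 ± 159, and smooth muscle markers 16.5 and 8.80 TPM, led by Acta2 at 75.0 ± 19.9. Adipocyte markers had medians of 9.08 and 10.5 TPM, led by Fabp4 at 200 ± 76.7, and macrophage and myeloid markers 4.75 and 3.70 TPM, led by Lyz2 at 84.5 ± 2.66.

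Outside the cell type lists, housekeeping genes had medians of 30.6 and 20.3 TPM, led by Eef1a1 at 1250 ± 79.4, and nuclear retained RNAs were led by Malat1 at 1045 ± 726. Immediate early genes had medians of 5.76 and 6.18 TPM, with Dusp1 at 21.6 ± 4.88, and RNAs without a poly(A) tail 6.76 and 21.7 TPM.

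Lists with a median under 1 TPM in at least one library were those of T cells and lymph node stroma, B and plasma cells, hepatocytes, intestinal epithelium, glia and neurons, proliferation, and the X and Y genes. Single members of these lists were well above it: the immunoglobulin gene Igkc reached 129 ± 50.9 TPM, Cd74 61.5 ± 6.06, Ttr 104 ± 12.8 and Trf 36.6 ± 4.14 (SD, n = 2). The liver gene Alb lay at 0.585 ± 0.0354 TPM, the intestinal gene Lyz1 at 3.70 ± 1.68, the neuronal gene Snap25 at 7.47 ± 4.70 and the proliferation gene Mki67 at 0.280 ± 0.156. Xist, the RNA of the inactive X chromosome, reached 92.8 TPM in replicate 1 and 86.4 TPM in replicate 2. Kdm5d, Uty, Ddx3y and Eif2s3y on the Y chromosome and Tsix had 0 counts in both libraries, where 0 allows up to 0.318 CPM in replicate 1 and 0.306 CPM in replicate 2.

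**Figure D2:**
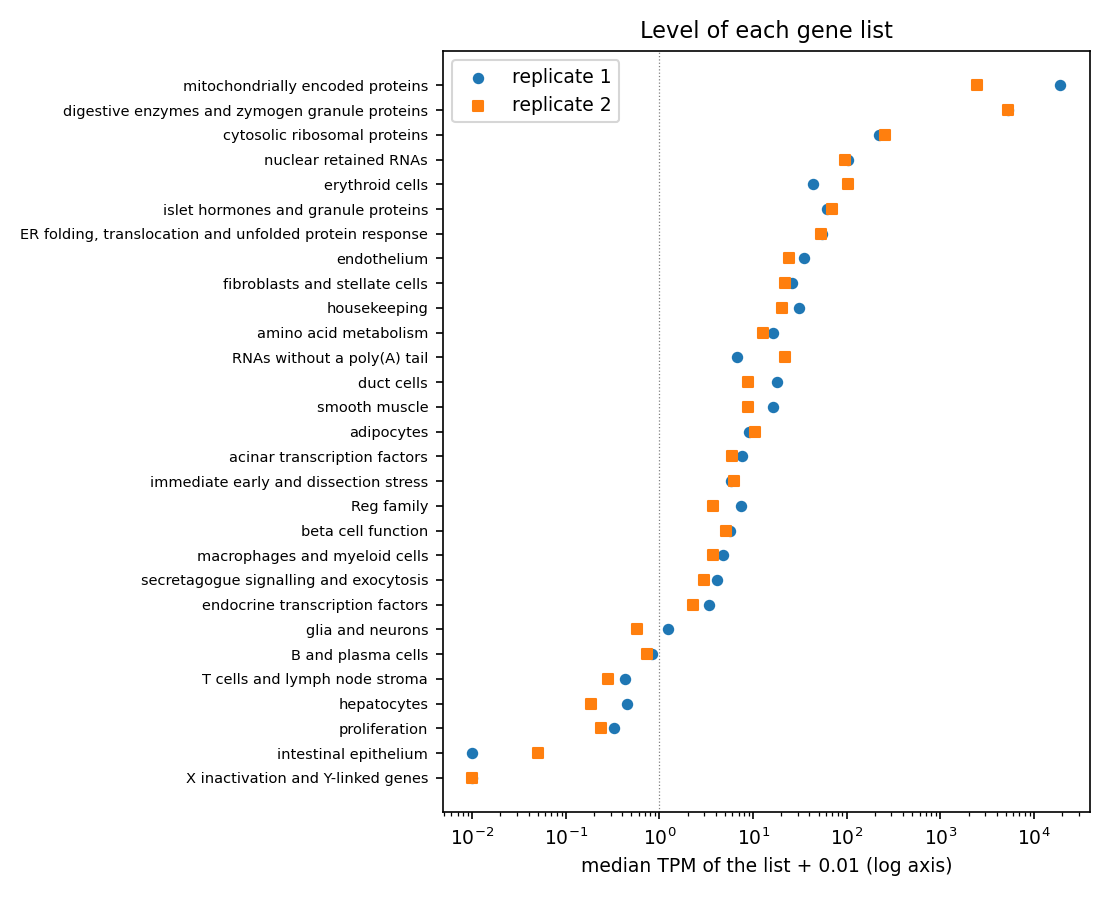
Median TPM of each fixed gene list plus 0.01 (x axis, log scale) in replicate 1 (circles) and replicate 2 (squares), with a dotted line at 1 TPM. Mitochondrially encoded proteins had medians of 19144 and 2435 TPM, and digestive enzymes 5334 TPM in both.

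The third question was how far 2 libraries of the same tissue sample differ. Whether both were made with the same poly(A) selection and read layout is not given in the sources used here, so a ratio may also reflect how a library was made. In replicate 2, 12 of the 13 mitochondrially encoded mRNAs were called lower, and the lincRNAs Gm42418 and Gm26917 and the mitochondrial leucyl-tRNA synthetase gene Lars2 were higher. The list median of these mRNAs was -2.14 on the log2 scale, and mt-Nd3, at 0.26, was not called. With the counts of its nuclear copy Gm28438 summed in, mt-Nd3 was at -0.92. Of the other groups, 4 hemoglobin genes, 19 of 81 tested ribosomal protein genes and the elastase genes Cela3b, Cela2a and Cela1 were called higher; with library totals 2 of the hemoglobin, 6 of the ribosomal protein and 0 of the elastase calls stayed, and after removal of a GC and length trend 2, 10 and 1. Among 12452 genes tested with the exact binomial test, 1533 were called, 1035 higher and 498 lower in replicate 2. The test holds counting error alone, with no replicate check, and compares these libraries and not conditions. An edgeR exact test with an assumed dispersion of 0.1 called 45 genes, and after removal of a GC and length trend 972 were called, 47.8% of them higher.

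**Figure D3:**
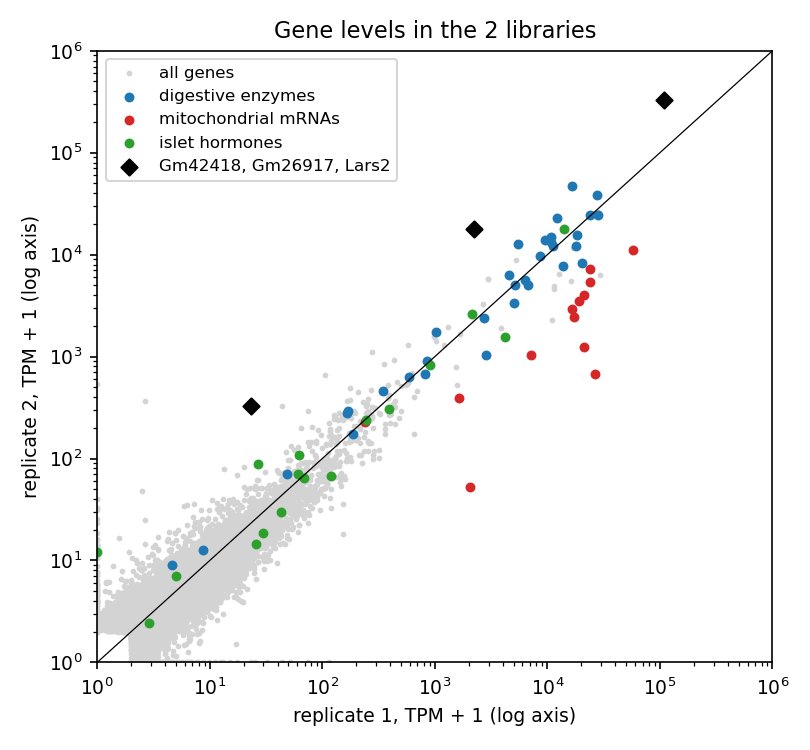
TPM + 1 of each gene at 1 TPM or more in either library, replicate 1 on the x axis and replicate 2 on the y axis, both log scales, with the line of equal values. Mitochondrial mRNAs lie below the line, mt-Nd3 closest to it, and Gm42418, Gm26917 and Lars2 lie above it.

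Direction here is relative to the TMM scaling: with library totals in place of TMM, all log2 ratios shift by -0.54, and 342 genes were then called higher and 2603 lower. The 12 mitochondrial mRNAs called lower stayed called under totals, with a list median of -2.68, and mt-Nd3 turned from above to below 0. The medians of the digestive enzyme and ribosomal protein lists turned to -0.14 and -0.02, and that of the immediate early list to -0.18.

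Among mitochondrial mRNAs, mt-Nd2 (chromosome M, 3914 to 4951) had a log2 ratio of -2.55 (95% exact interval -2.57 to -2.53) and mt-Nd5 (11742 to 13565) one of -2.49 (-2.52 to -2.47). mt-Nd4 lay at -2.23 (-2.25 to -2.21) and mt-Cytb at -1.89 (-1.91 to -1.88). The lowest values, -5.01 for mt-Co2, -4.94 for mt-Nd4l and -3.78 for mt-Co3, belong to genes that share sequence with nuclear copies, the most counted of them on chromosome 1. The copy of mt-Co2, Gm28661 (24614885 to 24615565), is identical to it over 681 bases. With the copies' counts summed in, the 3 ratios were -1.53, -2.12 and -1.08. That of mt-Nd3 turned from 0.26 to -0.92. Its copy Gm28438 held 18149 and 6671 counts, against 387 and 331 for mt-Nd3 itself.

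Among the 10 highest ratios was that of Pcsk1n (chromosome X, 7919822 to 7924410), a neuroendocrine granule gene, with 0 counts in replicate 1 and 170 in replicate 2, at least 79.2-fold higher against a floor of 3 counts per library, which leaves out counting error in the 170. Gm21887 had 4 and 886 counts, a log2 ratio of 8.10 (95% exact interval 6.91 to 10.15). Plac9b (5 and 163 counts), Med25 (20 and 112), the elastin gene Eln (52 and 214) and Gm20390 (30 and 119) were also among the 10 highest. The posterior standard deviation of the count was 7.63 and 31.0 for Plac9b and 15.7 and 18.9 for Gm20390, so the assignment of reads to these 2 genes was uncertain. Gm26917 (chromosome 17, 39843013 to 39846341) had a log2 ratio of 3.96 (95% exact interval 3.84 to 4.08) and Lars2 (chromosome 9, 123366927 to 123462666) one of 3.29 (3.28 to 3.30), from 72002 to 502775 counts. Gm42418 stood at 1.87 (1.87 to 1.88). At the other end, Gm15920 had 106 counts in replicate 1 and 0 in replicate 2, at least 25.3-fold lower against the same floor, Gm26870 had 140 and 4, and Gm2274 172 and 23, with a posterior standard deviation of 44.4 and 8.63. The identifier ENSMUSG00000103508.1, which has no symbol in the reference used, had 131 and 0 counts, with one of 23.8 and 5.36.

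Of the 25 lists with 3 or more tested members, 7 lay outside the central 95% of random lists matched on mean count. By chance 1.25 are expected if members vary independently, but members of a list can move together, so this number is only a guide. Few genes matched the most abundant members: 52 tested genes had a mean of 10000 counts or more. Their log2 ratio had a spread of 1.08, against 0.47 at 300 to 1000 counts. How closely the random lists matched the digestive enzyme and mitochondrial lists was not tested. The counts of called members were the same over all genes tested and adjusted over the list alone. The digestive enzyme list had a median log2 ratio of 0.40 (percentile 99.97), with 7 of 33 tested members called higher, 2 lower and 24 not called. The elastase genes Cela3b, Cela2a and Cela1 were 2.82-, 2.76- and 2.26-fold higher in replicate 2, while Pla2g1b and Rnase1 were 2.26- and 2.03-fold higher in replicate 1. With library totals 0 of the 7 higher calls stayed, and after the trend 3 did, those of Cela2a, Prss1 and Spink1, with Cela3b at 0.87 and Cela1 at 0.85, while the 2 lower calls stayed under both. Of 81 tested ribosomal protein genes, 19 were called higher and none lower, with a median of 0.52 (percentile 100), led by Rplp2 at 3.59, Rps29 at 2.97 and Rplp1 at 2.34. Of 6 tested erythroid genes 4, the hemoglobin genes Hbb-bt, Hba-a1, Hba-a2 and Hbb-bs, were called higher, at 1.63, 1.57, 1.40 and 1.33, with a list median of 1.37 (percentile 99.96). With library totals Hbb-bt and Hba-a1 stayed called, and after the trend Hbb-bt and Hbb-bs, with Hba-a1 at 0.98 and Hba-a2 at 0.85.

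Of 8 tested RNAs without a poly(A) tail, 5 were called higher, namely Rn7s1, Rn7s2, Rpph1, Rmrp and Hist2h2aa1, and none lower, with a median of 1.32 (percentile 100). Rn7s1 and Rn7s2 carry the same values, 2979 and 5814 TPM, because reads were divided between them. They are thus 1 observation counted as 2 members and 2 calls, and the list median of 1.32 is their shared ratio. The immediate early list had a median of 0.36 (percentile 97.9), with 4 of 16 members called higher, Junb, Ier2, Hspa1b and Ier3, and none lower. This call ended with a filter at a mean of 50 counts, where the percentile was 42.4, and after removal of the GC and length trend, at 85.2. The call of RNAs without a poly(A) tail also ended after the trend, at 93.9. Among members of these 2 lists, the calls of Ier3, Rn7s1 and Rn7s2 ended with library totals, and those of the same 3 and Rmrp after the trend. The endocrine transcription factor list was called lower, with a median of -0.43 (percentile 1.82). Of 11 tested members, Pax6 at -1.06 and Isl1 at -1.07 were called lower and Nkx6-1 at 1.04 was called higher. After the trend the list median was -0.71 (percentile 0.04), though Isl1 was then at -0.91 and not called. With the mean in place of the median the percentile was 2.59.

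The other 18 lists with a percentile lay between 3.86 and 95.9 and got no call, and 4 lists had too few tested members. Single members were called within them, Pcsk1n and Nkx6-1 as given above. Gcg fell by 1.19 on the log2 scale (interval -1.22 to -1.15) and Ppy had a log2 ratio of 2.07 (1.70 to 2.48), while Ins2 at 0.67 and Ins1 at 0.56 did not pass the size threshold. Ucn3 had -1.10 and Glp1r 1.63 among beta cell genes, Tie1 1.04 and Emcn -1.01 among endothelial genes, B2m -1.60 among housekeeping genes, and Phgdh 1.36 among amino acid metabolism genes. Hp, Orai1, Sdf2l1, Snap25 and Cd79a were the other called members of these lists, at 1.83, 1.86, 1.06, -1.09 and -1.38. After the trend the calls of Phgdh (0.87), Tie1 (0.51), Emcn (-0.91), Sdf2l1 (0.55), Snap25 (-0.87) and Nkx6-1 (0.37) ended, and with library totals those of Phgdh, Tie1, Sdf2l1 and Nkx6-1.

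The spread of the log2 ratio over all tested genes was 0.63, against 0.23 in counts drawn from a Poisson model. In genes with a mean count of 1000 to 10000 it was 0.56 against 0.05. Across 12124 genes at 1 TPM or more in either library, log2(TPM + 1) had a Pearson r of 0.903 and a Spearman rho of 0.844; genes are not independent replicates, so no p is given. The chi-square of the counts over tested genes was 246 per degree of freedom, and 31.4 without mitochondrial genes, their copies, Gm42418, Gm26917 and Lars2, so the libraries differ by more than sampling noise and were counted as 2 technical replicates of 1 sample.

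The last question was whether genes used the same main isoform. Among 3686 genes with enough counts, the share of the main isoform differed by 0.2 or more in 1282 genes, or 34.8%, and another isoform was most abundant in 1027. In Gbp7, a guanylate-binding protein gene, transcript Gbp7-201 held 100% of TPM in replicate 1 and 0% in replicate 2, where the gene had 88 counts. Sez6l-201 and Dagla-201 likewise held 100% and 0%, while Emc1-201 and Spry1-201 held 0% and 100%. These genes had 68 to 228 counts per library, and the assignment of reads to isoforms is model based, with no replicate error to set against it.

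**Figure D4:**
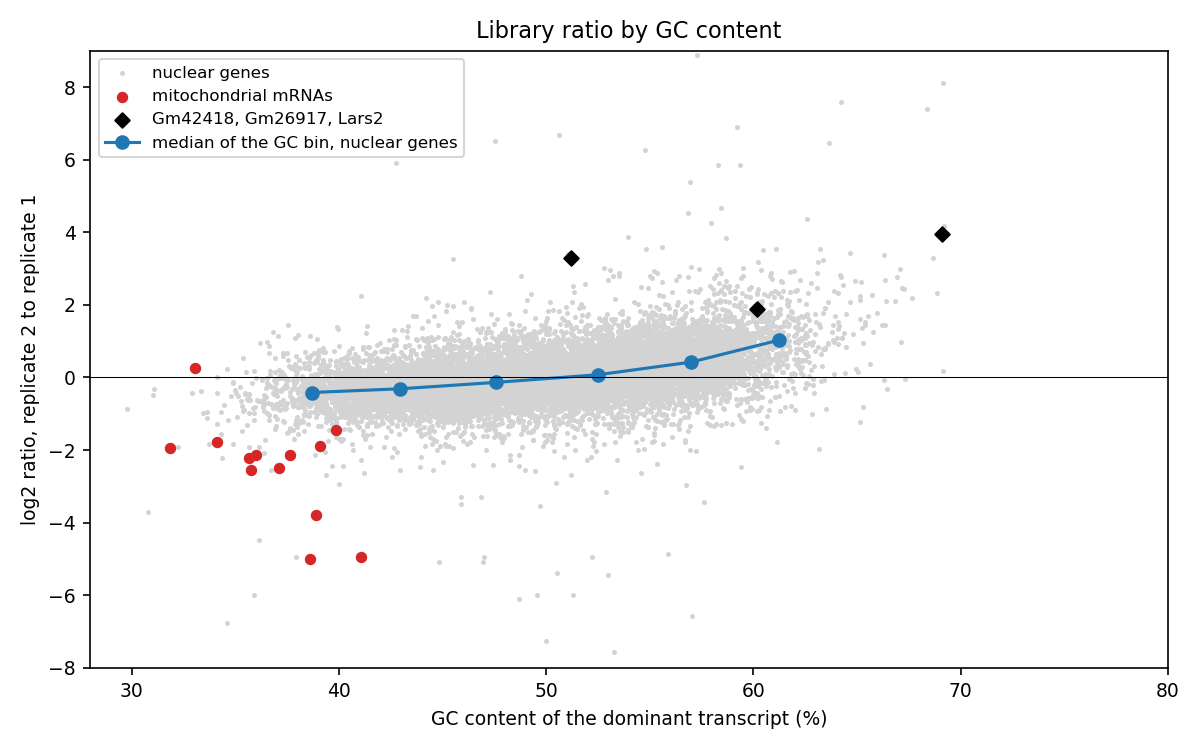
Log2 ratio of replicate 2 to replicate 1 (y axis) against GC content of the dominant transcript (%, x axis) for each tested gene, with the median ratio of nuclear genes in bins of GC content. The bin median goes from -0.41 under 40% GC to 1.03 at 60% or more, and mitochondrial mRNAs lie below it apart from mt-Nd3.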

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

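The number of genes called between the libraries depended on scaling and on the assumed spread. It was 2945 with library totals, 649 at a mean of at least 50 counts, where fewer genes were tested, 972 after the GC and length trend and 45 with an edgeR exact test at an assumed dispersion of 0.1. Of the 1533 main calls, 840 were shared with library totals and 724 with the trend. The share of calls higher in replicate 2 was 67.5%, against 11.6% with library totals and 47.8% after the trend; the cause of the other shifts was not tested. The other 7 settings gave 1238 to 1696 calls. No fit without either library is possible for this comparison, and no paired analysis was possible because there is 1 group.

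The number of genes detected in both libraries, 10332, fell to 3938 at 5 TPM. It rose to 12065 at 0.5 TPM and to 15343 with posterior mean TPM. The digestive enzyme share, 27.3% in replicate 1 and 31.1% in replicate 2, was 25.5% and 21.4% of counts (mean 23.5%) and 37.2% and 32.7% without mitochondrial genes in the total (35.0%), so the order of the libraries turned; it was 30.7% and 47.8% without Gm42418, Gm26917 and Lars2 (39.3%) and a mean of 37.2% with all Amy2a copies. With Gm42418, Gm26917 and Lars2 left out, the 10 most abundant genes other than Gm42418, which is 1 of them, held 32.6% of the remaining total. The settings without Gm42418, Gm26917 and Lars2, with all Amy2a copies and with near-identical copies summed were chosen after seeing the data. The spread was 0.85 without a count filter and 0.54 at a mean of 50 counts. Pearson r was 0.830 with a pseudocount of 0.1, 0.946 with 10, 0.936 over all genes with a count, 0.898 without the 10 most abundant genes and 0.897 without Gm42418, Gm26917, Lars2, mitochondrial genes and their copies. Isoform differences were found in 113 genes at a mean of 500 counts, where fewer genes were considered. They were found in 2176 genes at a share difference of 0.1 and in 946 with posterior mean TPM. The cause of these shifts was not tested.

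Among lists, the immediate early percentile changed side to 42.4 at a mean of 50 counts and was 85.2 after the trend, that of RNAs without a poly(A) tail was 93.9 after the trend, and that of endocrine transcription factors 2.59 with the mean. Lists that gained a call were islet hormones with the mean (99.99) and, after the trend, beta cell function (99.2), smooth muscle (0.79), B and plasma cells (2.32) and glia and neurons (0.895). The islet hormone mean of 0.74, against a median of 0.20, includes Pcsk1n at 8.90, which had 0 counts in replicate 1. Of 122 list percentiles under other settings, 113 kept their call or lack of one. Library totals shift all ratios alike and so could not change a percentile, and the percentiles under that setting say nothing about stability. Summing near-identical copies changed the counts of some mitochondrial mRNAs, Amy2a5 and their copies only, so the other lists could hardly move there. Both settings are among the 122, so 113 overstates how stable the calls were. The number of lists with a median of 1 TPM or more in both libraries was 22 to 24 and the number of list calls 6 to 9, but 36 of 116 list medians in TPM moved by more than their SD over the 2 libraries. Leaving out a library cannot move a median by more than this SD, so all of these moves came from the other settings. Depth limits low genes: 20.5% of tested genes in replicate 1 and 26.6% in replicate 2 had under 30 counts.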

Other observations

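Abundant genes outside the fixed lists, named after their values were seen, included Nupr1, a stress-response gene of the exocrine pancreas, at 2893 ± 1392 TPM (SD, n = 2 technical libraries). The translationally controlled protein gene Tpt1 reached 1672 ± 1.32 TPM and the ferritin heavy chain gene Fth1 389 ± 4.57. Dmbt1, a secreted mucosal glycoprotein gene, lay at 384 ± 58.4 TPM and Hamp2, a hepcidin family gene, at 266 ± 130. The ferritin light chain gene Ftl1 was called higher in replicate 2, at a log2 ratio of 1.36, and S100a11 lower, at -1.38.

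Except for the test of the mitochondrial tRNA synthetases, the tests below were chosen after related results had been seen, though the GC and length trend itself was planned. The GC test of Gm42418 and Gm26917 replaced a first one, on their ratios after the trend, 1.04 and 1.82, since the first gave no spread to set against those values. The test of the acinar share replaced one on the erythroid list, whose median was 0.91 after the trend, because that list had been picked for its rise; under its first bar, a median below 0, the values had gone with a larger share, and its fall among random lists and its second grouping were added after that was seen. Because the 2 libraries share 1 tissue sample, no biological explanation given by the design was tested.

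Gene groups differed between the libraries with GC content: across 12411 tested nuclear genes, the log2 ratio had a Spearman rho of 0.465 with GC content, and a GC and length trend held 24.2% of its variance. After the trend was removed, the lowest percentile of the digestive enzyme, ribosomal protein and erythroid lists was 99.97. For the ribosomal protein and erythroid lists, GC content and length are thus not the whole cause. For the enzyme list the random lists were not matched at its highest counts, so its percentile does not decide this. The higher of the immediate early and non-poly(A) percentiles was 93.9, from 97.9 and 100 before. Their medians were 0.12 and 0.28 against 0.36 and 1.32, though 3 of 4 and 2 of 5 of their called members stayed called. A larger share of acinar RNA in replicate 2 would lower the markers of all other cell types alike. With erythroid genes left out, 116 such markers had a median of -0.17 after the trend (percentile 1.89 of matched random lists). Endocrine cells (38 genes) and duct cells (15 genes) had medians of 0.04 and 0.15, not below 0 under TMM scaling. With library totals, which shift all log2 ratios by -0.54, both medians fall below 0. The endocrine median pools lists that differed after the trend. Endocrine transcription factors were at -0.71, islet hormones and granule proteins at 0.15 and beta cell function at 0.37. Smooth muscle (6 genes), B and plasma cells (5 genes) and glia and neurons (5 genes) were at -0.62, -0.70 and -0.87. Fibroblasts, endothelium, macrophages and adipocytes lay between -0.25 and -0.10. The difference between cell types lay at percentile 88.4 of random reassignments with the endocrine lists as 1 cell type but at 99.85 with them as 3. This share therefore cannot be told apart. Acinar genes did not move together after the trend, with the enzyme list at 0.37, acinar transcription factors at 0.01 (percentile 62.4), Rnase1 at -1.01 and Pla2g1b at -1.56, which a larger share does not account for by itself. What set the enzyme, ribosomal protein and hemoglobin genes apart stays open, and GC content is a candidate explanation for the medians of the immediate early and non-poly(A) lists, not for the ratios of all their called members.

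Of 13 mitochondrial mRNAs, 12 were called lower in replicate 2. The median share of GC-matched nuclear genes at or below each mRNA was 0%, over 12 mRNAs with a match, of which mt-Nd2, mt-Nd4, mt-Nd6 and mt-Atp8 had 16 or fewer matched genes, so GC content did not account for the fall. With nuclear copies summed in, the median of the 13 mRNAs was -1.94, so shared reads did not account for it either. Shared reads could account for the further fall of mt-Co2, mt-Co3 and mt-Nd4l: with copies summed the lowest of the 3 was -2.12, inside the range of the other 10, -2.55 to -0.92.

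Gm42418, Gm26917 and Lars2 were higher in replicate 2. Lars2 kept a log2 ratio of 3.28 after the GC and length trend, and the other 15 tested mitochondrial tRNA synthetase genes had a median of 0.29, with 3 called higher. Neither the GC content of its whole transcript nor a shared rise of this class accounts for the rise of Lars2. Where in Lars2 the reads came from was not determined, so a GC effect on a part of the transcript was not tested. For Gm42418, 2.95% of 305 GC-matched nuclear genes lay at or above its ratio, and Gm26917 had 2 matched genes, so a GC effect cannot be told apart there. The 3 ratios spread over 2.09, and after the trend Lars2, Gm26917 and Gm42418 stood at 3.28, 1.82 and 1.04. Because a GC effect was not separated from these ratios, their spread does not decide whether 1 RNA in fixed proportion was the source. Reads of ribosomal RNA, of 1 kind or more, may be behind them and stay open, since no ribosomal RNA sequence was used here. The annotated mitochondrial ribosomal RNA genes went the other way, with 2.70% of counts in replicate 1 and 0.877% in replicate 2.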
